A study of Escherichia coli with 3 samples.

How the data were processed

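Total RNA was extracted with TRIzol, per the labels, from E. coli TO114 grown at 37 °C in LBK medium with ampicillin (50 µg/ml) and kanamycin (25 µg/ml). The 3 libraries were the TO114 control (0 M NaCl, 4 h), the TO114+NhaC control (0 M NaCl, 4 h) and TO114+NhaC with 0.4 M NaCl (6 h), 1 library per group. The submitters' processing notes name Bowtie; its version is not given in the sources used here, nor are the read counter, the genome build and the strand of the reads. The deposited table gives read counts per coding sequence as count values, per the file headers, beside a Length column. It also gives deposited RPKM values and deposited TPM values for the same coding sequences. In all 4226 coding sequences the deposited RPKM and TPM equalled the values computed from the deposited counts and lengths, within a relative tolerance of 1e-06. All comparisons used the deposited counts, and RPKM and TPM were used for that check only.

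Library totals were 11713690 counts for the TO114 control, 11745376 for the TO114+NhaC control and 12677030 for the 0.4 M NaCl library, with medians of 426.5, 449.5 and 531.5 counts per coding sequence. The 10 most abundant coding sequences held 27.0%, 29.6% and 25.1% of the counts. Listed at 0 were 16, 17 and 12 coding sequences, 8 of them in all 3 libraries. The floor of 3 counts equals 0.282, 0.258 and 0.213 scaled CPM.

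Gene symbols were matched to the reference gene table by coding length or stop position together with the distances to flanking genes, of which at least 3 of 10 had to fit. The match gave symbols to 4165 coding sequences (98.6%), 3996 by length and 169 by stop position, and left 61 without. Where the product name ended in a symbol (112 coding sequences), 107 had the same symbol or a synonym and 5 differed. The tnaA gene was taken by its product name.

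Libraries were scaled by TMM (edgeR 4.0.16, R 4.3.3) over all coding sequences, with factors of 0.908, 0.991 and 1.11. Log2 ratios were taken of scaled counts with 0.5 added, and their intervals were exact Clopper-Pearson intervals (95%) of the share of the pair's counts. A coding sequence was measured when the pair held at least 50 counts, and called higher or lower at a ratio of at least 2. With 1 library per group there are no residual degrees of freedom, so no edgeR or DESeq2 test across genes was run. Percentages of lower genes are of the genes past 2-fold in either direction.

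Before the data were examined, the comparisons, the size rule, 48 gene lists and the naming rule were fixed. The comparisons were NhaC expression (TO114+NhaC control to TO114 control) and salt (0.4 M NaCl to TO114+NhaC control). Each list's median was placed among 10000 random lists matched on 20 bins of expression, and a list stood apart in the lowest or highest 1%. Genes of 1 operon vary together and some genes are in several lists, so the percentile is a description and not a test. The lists cover antiporters, K+ uptake, osmoprotectants, trehalose, channels, stress and envelope responses, the capsule, surface structures, porins, translation, energy metabolism, biosynthesis, sugar, glycerol and fatty acid use, decarboxylases, polyamines, efflux, cold shock, toxin-antitoxin pairs and metals. A list of stable RNA had no member in the table, and 47 lists were measured. Named genes were nhaA, nhaB and chaA, the 10 genes per direction with the most extreme interval bounds, up to 4 members per list with the largest ratios in the direction of its median, and 12 single genes (proP, betT, kdpA, otsA, osmY, rpoS, ompF, ompC, tnaA, lacZ, rmf and dps).

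Alternatives were scaling by total counts, by DESeq2 (1.42.0) size factors and by the upper quartile, a minimum of 10 or 200 counts or none, a ratio of at least 4, the whole interval beyond 2-fold, 5 added to each count, and libraries thinned to the smallest total. Chosen after the data were seen were the third library as the reference or numerator and the leaving out of coding sequences without a symbol or of insertion elements. The relation between the comparisons was set beside 100 simulated sets of unchanged libraries.

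The computation was tested on simulated data, with Poisson counts at the observed means and 200 genes changed. In the NhaC comparison (3901 genes measured) 4-fold changes had median log2 estimates of 1.99 and −1.96 and 2-fold changes 1.00 and −1.02, and in the salt comparison (3922 genes) they were 2.00 and −2.00, and 0.98 and −0.99. Of unchanged genes, 2 of 3701 and 1 of 3722 passed 2-fold, and 95.8% and 95.3% of intervals held the true ratio. Of genes changed 2-fold, 54% and 41% passed the rule, and of those changed 4-fold 100% did in both. The simulated counts held counting error only, so these rates do not cover variation between cultures. Of 200 lists of unchanged genes, 2 and 4 stood apart. Further tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.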

Results

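Transcripts were counted in 3 libraries of E. coli TO114, a strain known to carry disruptions of the antiporter genes nhaA, nhaB and chaA. TO114 without NhaC (TO114 control) and TO114 expressing the NhaC antiporter (TO114+NhaC control) were sampled after 4 h without added NaCl, and TO114 expressing NhaC was also sampled after 6 h with 0.4 M NaCl. Each group was 1 library, so no replicate check was possible and no p-value is given. Intervals are 95% intervals that cover counting error only.

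The disrupted antiporter genes all carried counts. nhaA had 509 counts in the TO114 control, 655 in the TO114+NhaC control and 718 in the 0.4 M NaCl library, and nhaB had 297, 378 and 453. Their log2 ratios were 0.23 and 0.22 with NhaC and −0.14 and −0.01 with salt, where the sign of both depended on the scaling. chaA had 111, 266 and 631 counts and was higher in each successive library, by 1.13 (0.81 to 1.46) with NhaC and by 0.97 (0.76 to 1.18) with salt. Counts over these genes do not check the genotype. The 4226 coding sequences counted are those of the E. coli chromosome and include none for the introduced antiporter.

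With NhaC and no added salt, the outer membrane protein gene ompW, the selenate reductase genes ynfE, ynfF and ynfG, hydrogenase 2 genes (hybO, hybA, hybB) and galactitol transporter genes led the higher side. Prophage lysis and tail genes such as rzpD and tfaQ and the stress operon yciGFE led the lower side. Colanic acid capsule genes and RpoS-dependent stress genes were lower as lists, and the methionine synthesis genes metE, metF and metA were lower as well. Anaerobic respiration genes went both ways, more of them higher than lower.

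Of 3902 coding sequences with at least 50 counts in the pair, 233 were at least 2-fold higher in the TO114+NhaC control than in the TO114 control and 548 at least 2-fold lower (70.2% lower). Scaling by total counts gave 320 higher and 472 lower (59.6% lower) and moved every log2 ratio up by 0.13. The whole counting interval lay beyond 2-fold for 129 higher and 416 lower coding sequences, and 29 were at least 4-fold higher against 245 at least 4-fold lower.

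**Figure D1:**
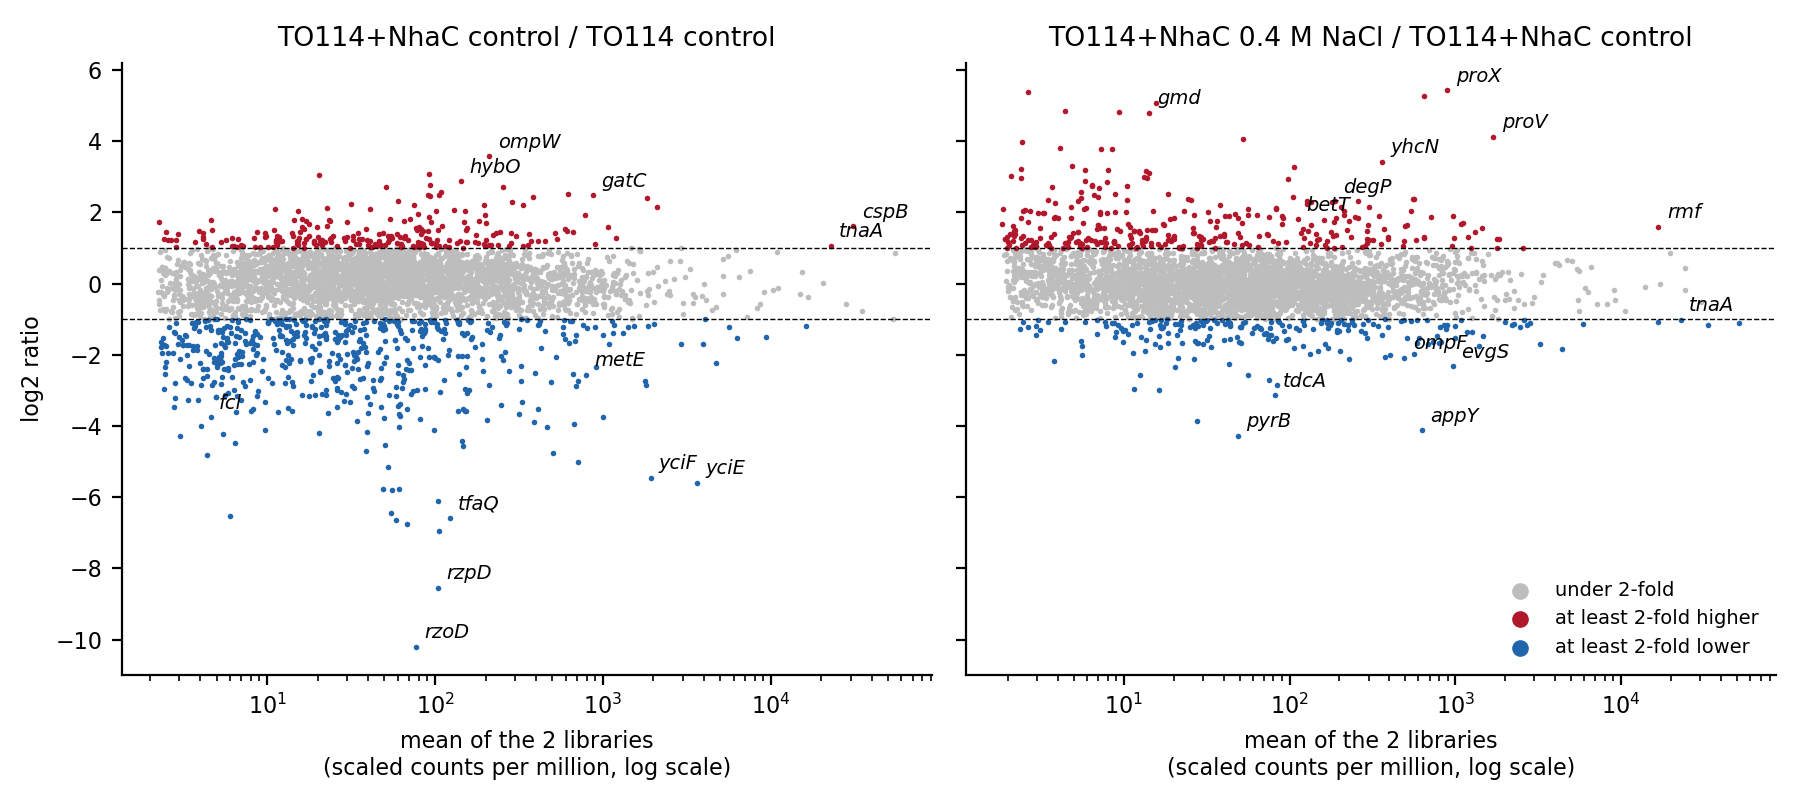
Log2 ratio (vertical axis) against the mean of the 2 libraries in scaled CPM (horizontal axis, log scale), 1 point per coding sequence with at least 50 counts in the pair, with dashed lines at 2-fold; the left plot compares the TO114+NhaC control with the TO114 control and the right plot compares 0.4 M NaCl with the TO114+NhaC control. The left plot has 548 points at or below the lower line and 233 at or above the upper line, and the right plot has 218 and 319.

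ompW, which encodes a small outer membrane porin, had 346 counts in the TO114 control and 4536 in the TO114+NhaC control, a log2 ratio of 3.58 (3.43 to 3.75). Genes of the selenate reductase operon followed, with ynfE at 3.08 (2.88 to 3.30), ynfG at 3.04 (2.61 to 3.52) and ynfF at 2.76 (2.58 to 2.96). Subunit genes of hydrogenase 2, which takes up hydrogen, were higher by 2.89 (hybO, 361 to 2923 counts), 2.71 (hybB) and 2.57 (hybA). The galactitol transporter had log2 ratios of 2.49 for gatC, which had 2813 and 17320 counts, 2.51 for its EIIB component and 2.71 for its EIIA component. cspB, a cold shock protein gene, was among the most abundant transcripts and was higher by 1.61, from 162440 to 543680 counts. tnaA, which encodes tryptophanase, was higher by 1.06, from 156844 to 358491 counts.

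The 10 coding sequences with the lowest upper bounds were 8 prophage genes, yciE and yciF. rzoD, a lysis lipoprotein gene, had 1638 counts in the TO114 control and 1 in the TO114+NhaC control (log2 ratio −10.20, −16.11 to −8.33). The endopeptidase gene rzpD, in which rzoD lies, was at −8.54, the packaging gene nohD at −6.96, the paired lysis genes rzpR and rzoR at −6.76 and −6.65, the tail fibre genes tfaQ and tfaR at −6.58 and −6.12 and the exonuclease gene exoD at −6.44. Several of these genes overlap or have near-identical copies in other prophages, so the split of counts among them is uncertain. yciE and yciF, whose products are stress proteins of unknown role, had 75704 and 40007 counts in the TO114 control and 1719 and 1000 in the TO114+NhaC control (−5.59 and −5.45).

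Among 47 gene lists, 6 had medians in the outer 1% at either end of matched random lists. Lists of independently varying genes would give 0.94, but genes of 1 operon vary together, so the 6 are a description and not a test. Anaerobic respiration and fermentation was high (median 0.43, above 99.9% of random lists), with 13 of 29 genes higher, 6 lower and 10 neither; hyaB of hydrogenase 1 was at 2.29, dmsB of dimethyl sulfoxide reductase at 2.23 and the asparaginase gene ansB at 2.21, while the nitrite and nitrate reductase operon genes nirB, nirD and napF, named after their values were seen, were at −3.04, −2.88 and −1.92. NADH dehydrogenases had a high median (0.43, above 99.7%) with none of 15 genes past 2-fold; the complex I subunit genes nuoB and nuoA were at 0.86 and 0.77, while ndh, of the second enzyme and named after its value was seen, was at −0.76. Colanic acid capsule genes of the Rcs pathway were low (median −2.01), with 15 of 16 lower, among them the sugar nucleotide genes fcl at −3.75 and gmd at −3.62 and the glycosyltransferase gene wcaA at −2.84; gmd had 11 counts and fcl 7 in the TO114+NhaC control, and at a minimum of 200 counts this list no longer stood apart. The general stress genes that depend on RpoS were low (median −0.60), with 11 of 33 lower, none higher and 22 neither, led by the yciGFE genes and by the morphogene bolA at −1.71. No random list had a median as low as these 2 lists. Glutamate-dependent acid resistance (median −0.56) lay at the edge, above 1% of random lists, with 1 of 15 genes lower, the inner membrane protein gene yhiM at −1.69. Fatty acid degradation (median −0.55, above 0.815%) had 3 of 9 genes lower, 1 higher and 5 neither; the uptake gene fadL was at −1.44 and the thiolase gene fadA at −1.14. All 6 kept their direction under each scaling, but with the 0.4 M NaCl library in place of the TO114+NhaC control the medians turned for colanic acid (0.96), fatty acid degradation (0.75) and anaerobic respiration (−0.23).

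The lists that follow held genes with large ratios but did not stand apart from random lists. Methionine and cysteine synthesis had 8 of 27 genes lower and none higher around a median of −0.02, which total-count scaling placed above 0; the methionine synthase gene metE was at −2.56, metF at −2.44, metA at −2.05 and the taurine uptake gene tauA at −2.86. Galactose, galactitol and ribose use (median −0.24) had 4 of 19 higher and 2 lower, with the galactose gene galT at −2.12. Curli, an adhesive fibre, had 3 of 5 genes lower (median −1.82, csgA −2.47). Outer membrane porins had 2 of 12 higher and 4 lower (median −0.56, ompL −4.10). Phage shock had 2 of 7 higher (median 0.59, pspG 1.78), multidrug efflux 5 of 26 higher (median 0.17, marR 1.49), and glycerol use 1 of 11 higher (median 0.55, glpC 1.11). Tryptophanase and amino acid decarboxylases had 4 of 12 lower and 1 higher, the tryptophanase gene tnaA. The median was −0.12, above 0 under total counts, and the lysine decarboxylase operon genes cadB and cadA were at −2.07 and −1.53.

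The Na+/H+ and K+/H+ antiporter list did not stand apart (median 0.28), and its 1 higher gene of 12 was the disrupted chaA. Under total counts 2 of its genes were higher. K+ uptake (1 of 8 lower, 0 under total counts, −0.31), osmoprotectant uptake (3 of 13 lower, 0.02) and trehalose (2 of 7 higher, 0.15, with treC of trehalose breakdown at 1.49) did not stand apart either. Nor did mechanosensitive channels (1 of 8 higher, 0.03), oxidative stress (1 of 20 lower, 0.23) and iron uptake (2 of 25 lower, 0.04). Type 1 fimbriae (3 of 7 lower, −0.65) and ribosome hibernation and stationary phase (3 of 9 lower, −0.52) did not either. Flagella and chemotaxis had only 17 of 45 genes measured, 3 higher and 1 lower (0.23), and did not stand apart. Not measured were, among others, the master regulator genes flhD and flhC, of a run of 10 genes holding 1 count in each library. Of the biosynthesis lists, histidine and arginine had 3 of 21 higher and 1 lower (0.14). Branched-chain amino acids had 1 of 15 higher and 3 lower (−0.03, above 0 under total counts). Glutamate, glutamine and proline had 1 of 15 higher and 2 lower (−0.16). Purines had 1 of 15 higher (0.46, purT at 1.43), and pyrimidines 2 of 14 lower (−0.22, with 0 lower under total counts). This set held phosphate starvation (1 of 15 higher and 1 lower, −0.36) and the lac operon with lacI (2 of 4 lower, −0.88). The repressor gene lacI itself was at 20386 scaled CPM in the TO114 control and 20727 in the TO114+NhaC control. Polyamines (3 of 19 lower, −0.32) and cold shock (1 of 12 higher, 0.33) belonged to the set as well. Metal transport and response (3 of 23 higher and 4 lower, −0.08, above 0 under total counts) completed it.

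No gene passed 2-fold in heat shock (18 genes, median −0.10) or the TCA cycle (16, −0.07), both above 0 under total counts. The same held for envelope stress (20, 0.11), SOS response (16, 0.12), ribosomal proteins (54, −0.18), translation factors (12, −0.22), ATP synthase (9, 0.18), terminal oxidases (10, 0.07), glycolysis (16, −0.45), aromatic amino acids (14, 0.45), maltose use (12, −0.29), fatty acid synthesis (13, 0.34) and toxin-antitoxin pairs (20, −0.24). Under total counts 1 aromatic amino acid gene was higher. The proU operon, for osmoprotectant uptake, gave the 3 lower genes of its list, proX at −2.55, proW at −1.81 and proV at −1.28. Other single genes were closer between these libraries: the osmoprotectant transporter gene proP was at 0.02, the choline transporter gene betT at 0.40 and the trehalose synthesis gene otsA at 0.15. The porin genes ompF and ompC were at 0.08 and −0.18, the periplasmic stress gene osmY at −0.51, the ribosome dimer gene rmf at −0.24, the DNA-binding gene dps at −0.38, lacZ at −0.74 and the sigma factor gene rpoS at 0.89.

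With 0.4 M NaCl, the library held far more transcript for glycine betaine and proline uptake, the colanic acid capsule and the phage shock response, and less for the pyrimidine synthesis genes pyrB, pyrI and carA and the porin OmpF. The proU operon (proVWX) led the higher side. Against the TO114 control the capsule difference was smaller, with a list median of 0.96 and 8 of 20 genes higher, 1 lower and 11 neither. The TCA cycle, fatty acid degradation and branched-chain amino acid lists had high medians, with part of their genes past 2-fold. Salt and sampling time (4 h and 6 h) differed together in this comparison.

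Of 3924 coding sequences with at least 50 counts in the pair, 319 were at least 2-fold higher in the 0.4 M NaCl library than in the TO114+NhaC control and 218 at least 2-fold lower (40.6% lower). Scaling by total counts gave 433 higher and 141 lower (24.6% lower) and moved every log2 ratio up by 0.16. The whole interval lay beyond 2-fold for 193 higher and 142 lower, and 75 were at least 4-fold higher against 21 at least 4-fold lower.

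proX, which encodes the binding protein of the ProU transporter, had 474 counts in the TO114+NhaC control and 24656 in the 0.4 M NaCl library, a log2 ratio of 5.42 (5.30 to 5.56) or 43.0-fold. Against the TO114 control, with 2544 counts, proX was higher by 2.87 (2.81 to 2.93). Its operon partners proW and proV were at 5.27 (5.12 to 5.42) and 4.13 (4.07 to 4.20), and at 3.46 and 2.85 against the TO114 control. The choline transporter gene betT was at 1.81 (1.68 to 1.94) and betB, of glycine betaine synthesis, at 2.31 (2.19 to 2.42), while proP was at −0.40. The capsule sugar genes gmd and fcl had 11 and 7 counts in the TO114+NhaC control and 387 and 253 in the 0.4 M NaCl library (both 4.81). yjbE, of an exopolysaccharide operon, was at 4.05, the fimbrial gene yfcV at 5.08 (4.25 to 6.22) and the periplasmic stress gene yhcN at 3.42. matA, a fimbrial regulator gene, had 1 and 73 counts (5.39, 3.39 to 11.24), and yaiS, of unknown role, had 3 and 120 (4.85, 3.47 to 7.35). rmf was higher by 1.60, from 97293 to 357431 counts, rpoS by 1.45, from 8167 to 27071, and osmY by 1.01.

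appY, an anaerobic regulator gene, was at −4.12 (−4.22 to −4.03), from 13859 to 963 counts. The aspartate carbamoyltransferase genes pyrB and pyrI were at −4.27 (1076 to 67 counts) and −3.85, their leader gene pyrL at −2.99 and carA, for carbamoyl phosphate synthesis, at −2.72. purT, for purine synthesis, was at −2.95, the threonine breakdown regulator gene tdcA at −3.14, the regulator gene yqeI and its neighbour yqeJ at −2.55 and −2.86, and the acid sensor kinase gene evgS at −2.33. ompF was at −2.08 (−2.14 to −2.02), from 9279 to 2657 counts, with ompC at −0.19. tnaA was at −1.01, under 2-fold with total counts, and lacZ at −0.83, while otsA was at 0.34; dps was at −0.11, above 0 under total counts. kdpA, a K+ uptake gene, had 6, 7 and 9 counts in the 3 libraries and was not measured.

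**Figure D2:**
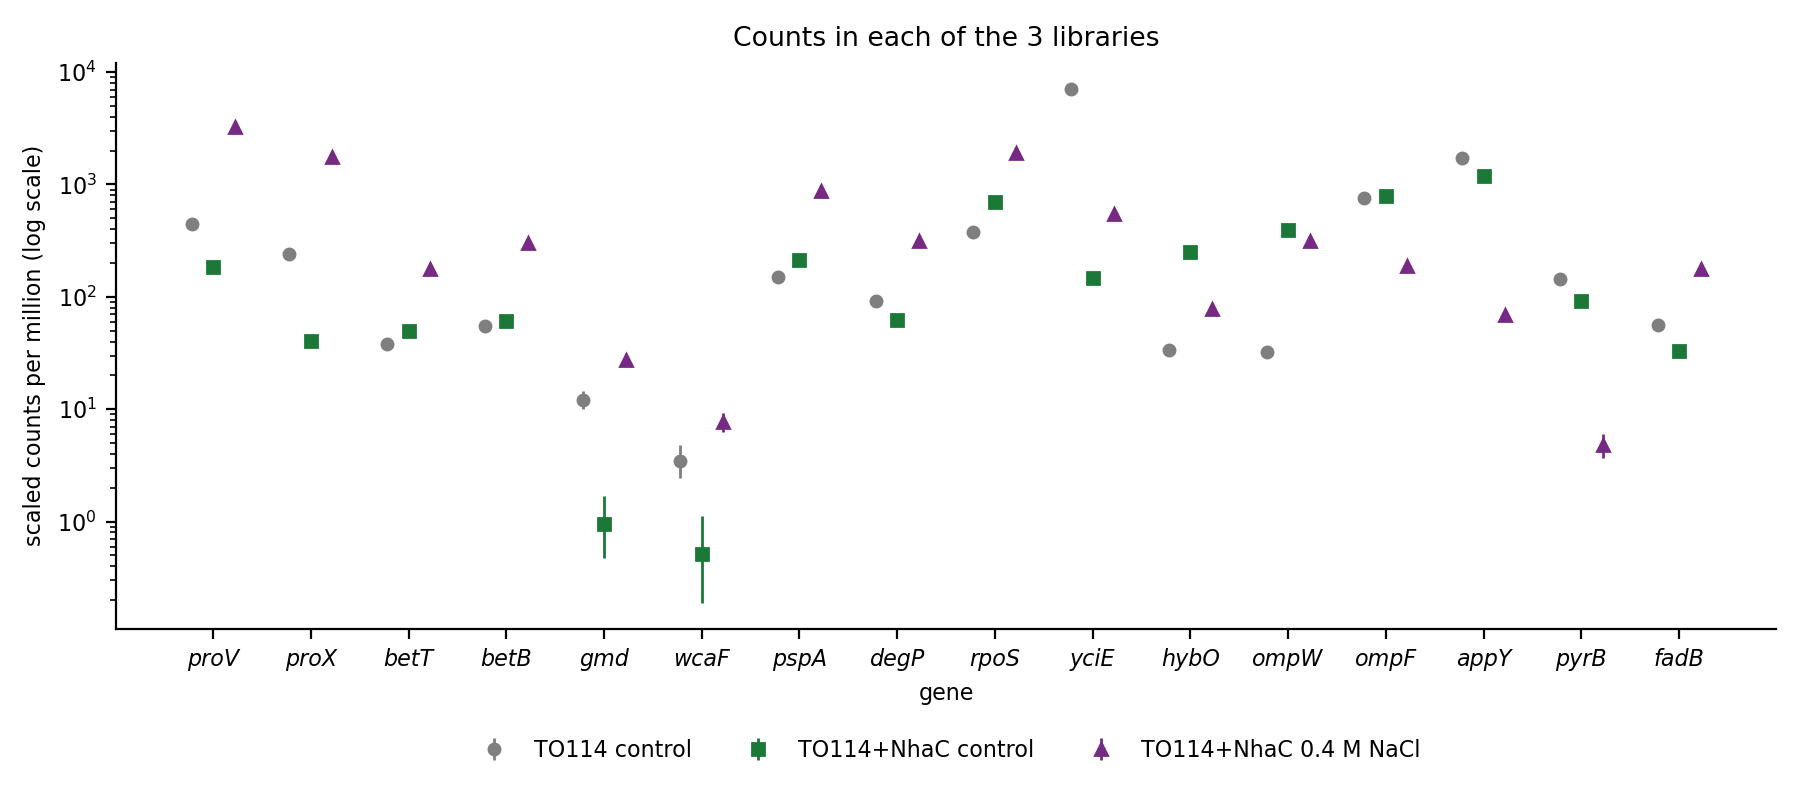
Scaled CPM (vertical axis, log scale) of 16 genes (horizontal axis) in the TO114 control (circles), the TO114+NhaC control (squares) and the 0.4 M NaCl library (triangles), with bars for the 95% counting interval of each value. proX had 2544, 474 and 24656 counts in these libraries before scaling, and ompW had 346, 4536 and 4413.

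In this comparison 14 lists stood in the outer 1% at either end of matched random lists, 9 high and 5 low, and each kept its direction under each scaling. All 20 colanic acid genes were higher (median 2.98), with the acetyltransferase genes wcaB at 3.97 (2.55 to 6.48) and wcaF at 3.80; against the TO114 control, 8 of 20 were higher, 1 lower and 11 neither (median 0.96), the lower 1 being the regulator gene rcsA at −1.42. Phage shock had 5 of 7 higher (median 2.04); the membrane stress genes pspB, pspC, pspD and pspA lay between 2.04 and 2.14. Osmoprotectant uptake and glycine betaine synthesis had 7 of 13 higher and none lower (median 1.81). Fatty acid degradation had 4 of 9 higher (median 0.90), with the oxidation genes fadB at 2.43 and fadE at 2.16. The TCA cycle had 6 of 16 higher (median 0.84), led by the succinate dehydrogenase genes sdhD at 1.91 and sdhA at 1.86. Branched-chain amino acid synthesis had 7 of 16 higher (median 0.73), among them the leucine genes leuB at 2.38 and leuA at 2.03.

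Phosphate starvation had 7 of 15 higher (median 0.56, above 99.5% of random lists, but 0.22 and not apart against the TO114 control), with the glycerol phosphate uptake genes ugpA at 2.14 and ugpB at 1.92 and the phosphate-binding protein gene pstS at 1.42. RpoS-dependent genes had 8 of 33 higher, 2 lower and 23 neither (median 0.38), with yciF at 2.33 and the catalase gene katE at 1.67; against the TO114 control the list was low (median −0.48, 1 higher and 9 lower) and yciF was at −3.13. Ribosomal proteins had 6 of 54 higher (median 0.36, 10 of 54 higher under total counts), with rpsS at 1.30 and rplB at 1.28. On the low side, anaerobic respiration had 7 of 30 lower (median −0.78, 3 of 30 lower under total counts), with hybO at −1.70 and ansB at −1.23; against the TO114 control its median was −0.23 and it did not stand apart. Maltose use had 4 of 12 lower (median −0.58), with the transport genes malK at −1.68 and lamB at −1.65. Acid resistance had 4 of 15 lower (median −0.57, 1 of 15 lower under total counts), with yhiM at −1.20. Purine synthesis had 6 of 15 lower (median −0.55, 4 of 15 under total counts), with purD at −2.10 and purH at −1.67, and did not stand apart against the TO114 control (median −0.28). Pyrimidine synthesis had 5 of 14 lower (median −0.53).

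**Figure D3:**
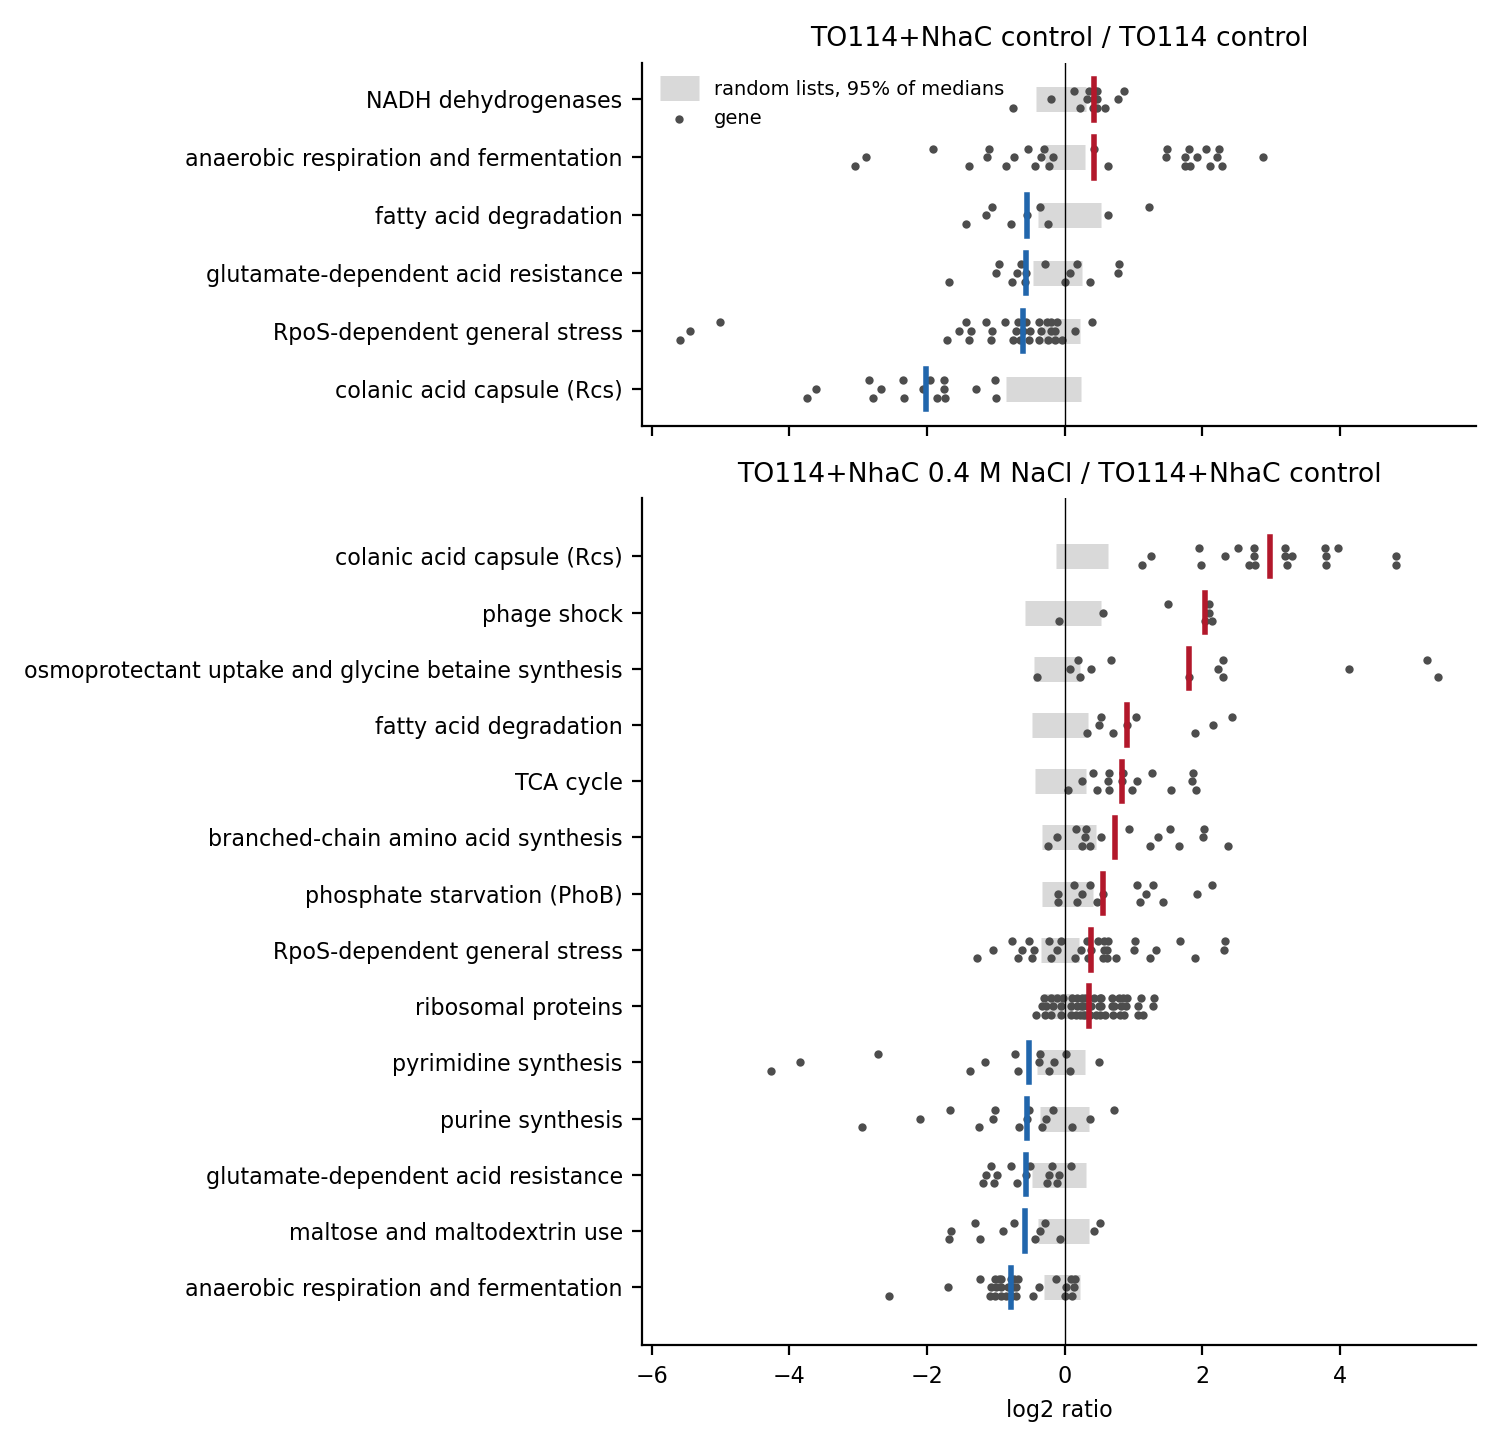
Log2 ratio (horizontal axis) of each measured gene (points) in the gene lists (vertical axis) whose medians (coloured ticks) lay in the outer 1% of random lists, with grey bars for the central 95% of random medians; the upper plot compares the TO114+NhaC control with the TO114 control and the lower plot compares 0.4 M NaCl with the TO114+NhaC control. The median of the colanic acid list was −2.01 in the upper plot and 2.98 in the lower plot.

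Envelope stress had 5 of 20 genes higher around a median of 0.04, led by the periplasmic protease gene degP at 2.32 and the chaperone gene spy at 2.15. Multidrug efflux had 4 of 26 higher and 2 lower (median 0.03, with the regulator genes marB, marA and marR at 1.71, 1.38 and 1.32). Glycerol use had 4 of 11 higher (median 0.43, the glycerol channel gene glpF at 1.85). Outer membrane porins had 4 of 12 higher and 2 lower (median 0.48, ompL 1.83). Tryptophanase and amino acid decarboxylases had 5 of 12 lower (2 under total counts, median −0.42, cadA −2.34), with tnaA and tnaC among them. Galactose, galactitol and ribose use had 6 of 19 lower (3 under total counts) and 1 higher (median −0.24, gatC −1.53). Methionine and cysteine synthesis had 5 of 27 lower (3 under total counts) and 1 higher (median −0.17, metF −1.60, metK −1.32). Type 1 fimbriae had 3 of 7 lower (median −0.39, with the subunit gene fimA at −1.59), and curli 1 of 4 lower (median −0.28, its regulator gene csgD at −1.75).

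The remaining lists did not stand apart. Antiporters had 0 of 12 genes past 2-fold (2 higher under total counts) and a median of −0.05 that was positive under total counts. Medians also turned positive under total counts for oxidative stress (1 of 20 higher, −0.10) and flagella and chemotaxis (2 of 18 lower, −0.08). They did so too for ribosome hibernation and stationary phase (2 of 9 higher, rmf and rpoS, −0.04) and ATP synthase (0 of 9, −0.04). The same held for terminal oxidases (3 of 10 higher and 2 lower, −0.07). There cydB of cytochrome bd was at −1.16, under 2-fold with total counts. Others were fatty acid synthesis (0 of 13, −0.06) and cold shock (3 of 12 lower, −0.04, cspI at −1.85). Metal transport and response (2 of 21 higher and 3 lower, −0.14) had a median that turned positive as well. No gene passed 2-fold in K+ uptake (8 genes, 0.19), mechanosensitive channels (8, 0.32), SOS response (16, 0.27) or translation factors (12, 0.10). The same was true of NADH dehydrogenases (15, 0.10), glycolysis (16, −0.19), the lac operon with lacI (4, −0.58) and toxin-antitoxin pairs (20, 0.18). Under total counts 1 gene was higher in each of mechanosensitive channels and SOS response. Trehalose had 1 of 7 lower (0.34), and 0 under total counts or the upper quartile. Heat shock had 1 of 18 higher (2 under total counts, 0.22, the protease gene htpX at 1.48). Iron uptake had 1 of 26 higher (3 under total counts, 0.04, fhuF at 2.01). A few genes passed 2-fold in histidine and arginine (2 of 22 higher and 2 lower, 0.12), aromatic amino acids (1 of 14 higher, 0.15), glutamate, glutamine and proline (2 of 14 higher, 0.18) and polyamines (4 of 19 higher, 0.14).

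Many genes lay on opposite sides in the 2 comparisons. Among 3855 coding sequences measured in both, 125 were lower with NhaC and higher with salt, where independent lists would give 38.0, and 57 were higher with NhaC and lower with salt, where they would give 13.2. Only 10 were higher in both and 24 lower in both, where independent lists would give 17.6 and 28.4. Because the TO114+NhaC control enters both comparisons in opposite roles, counting error alone gives opposite signs, and libraries simulated without change gave 0.06 and 0 such genes and a covariance of −0.00946 against −0.282 observed. That simulation covers counting error only, and variation between cultures in the shared library would also give opposite signs. The correlation was −0.381 across coding sequences and −0.511 in the simulated libraries. fcl, gmd and yciF were among the genes lower with NhaC and higher with salt, and hybO, gatC and purT were among those higher with NhaC and lower with salt. Between the outer libraries, 0.4 M NaCl against the TO114 control, fcl was at 1.05, gmd at 1.18, yciF at −3.13, hybO at 1.19, gatC at 0.96 and purT at −1.52.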

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

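No paired analysis was possible because each group was 1 library. Under the alternatives fixed in advance, 36 of the counts of genes and lists stayed within 1.5 times the main count and 8 did not. Those were, for the ratio of at least 4, 29 higher and 245 lower with NhaC and 75 higher and 21 lower with salt; for the whole interval beyond 2-fold, 129 higher with NhaC and 193 higher and 142 lower with salt, as stricter rules allow fewer genes; and for scaling by total counts, 141 lower with salt. Named gene values moved beyond their counting interval in 258 cases and stayed in 1832, and 23 of 214 values past 2-fold were under it in at least 1 setting. List medians moved in 97 cases and stayed in 372, and none of those standing apart changed sign. A minimum of 200 counts dropped the colanic acid list from those standing apart with NhaC (3 low lists), while all other lists standing apart did so at minimums of 10 and 200, and flagella, porins, glycerol use or type 1 fimbriae joined them in some settings. After seeing the data, the third library was also exchanged in. With the TO114 control in place of the TO114+NhaC control, 335 genes were higher and 551 lower with salt, of which 132 and 107 were shared with the 319 and the 218; the RpoS list stood apart on the low side (−0.48), and purine synthesis (−0.28), anaerobic respiration (−0.23) and phosphate starvation (0.22) no longer stood apart. With the 0.4 M NaCl library in place of the TO114+NhaC control, 93 of the 233 higher genes and 378 of the 548 lower genes were shared, and the medians with NhaC were 0.96 for colanic acid, −0.23 for anaerobic respiration and 0.75 for fatty acid degradation. The cause was not tested. TMM over every gene with stable RNA was not run, because the table holds coding sequences only. Depth limits genes under 50 counts in the pair, such as kdpA.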

Other observations

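All tests in this part were chosen after the pattern they address was seen. The H-NS target list was not among the gene lists fixed in advance. Only its prediction with NhaC was written before the values of its members were seen.

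More genes were lower than higher with NhaC, and the 548 lower genes had a median log2 ratio of −1.83. Genomic DNA in the TO114 control could raise silent genes there, but it adds a similar density everywhere, and 43.1% of the other coding sequences lay below the median density added to the lower genes (34.5 scaled CPM per kb). This argues against DNA as the whole cause. A list of 48 genes often described as H-NS targets, written before their values were seen and with 1 gene also in another list, had a median of −1.94 over 42 measured genes, 33 lower and 0 higher, and no random list lay lower (percentile 0). Some members share operons with genes already seen, and without the cas and sfm loci the median of 34 genes was −1.89, and again no random list lay lower. Less transcript of hns, which encodes the silencer H-NS, could be a reason; hns stood at 1967, 3068 and 1360 scaled CPM in the 3 libraries. In the 0.4 M NaCl library the H-NS target list was at −1.50 against the TO114 control, and at 0.15 against the TO114+NhaC control, but the hns paralogue stpA was higher there by 1.20 than in the TO114 control, so the part of hns stays open. Weaker silencing of such loci in the TO114 control may therefore account for part of the difference, and whether it follows from the absence of NhaC or belongs to that 1 culture stays open.

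Lists higher with salt could reflect a low value in the shared TO114+NhaC control alone. Against the TO114 control the medians were 2.66 for phage shock, 2.15 for osmoprotectants, 0.96 for colanic acid, 0.81 for the TCA cycle, 0.79 for branched-chain amino acids and 0.75 for fatty acid degradation, which argues against that explanation as the whole cause for these lists. Phosphate starvation (0.22) did not stand apart against the TO114 control, which goes with that explanation. With 1 library per group this does not settle it. For the RpoS list (−0.48), which was low there, and ribosomal proteins (0.16) the explanation stays open. Cells further into stationary phase at 6 h might also be considered, since rmf and rpoS were higher. Ribosomal protein transcripts are expected to be lower then. Under every scaling their medians were at least 0.357 against the TO114+NhaC control and 0.161 against the TO114 control. These are small shifts between single libraries, with 0 of 54 genes past 2-fold against the TO114 control, so they cannot decide this question. Salt, the subject of the design, and the 2 h of added time stay open together.

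lacI, which encodes the lac repressor, was among the most abundant transcripts, with 216939, 241256 and 392339 counts (1.85%, 2.05% and 3.09% of each library). Its density was 211, 186 and 272 times that of mhpR, the denser of its neighbours mhpR and lacZ. No explanation of this was tested.

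A run of 10 neighbouring coding sequences from cheB to flhD (positions 1969166 to 1979920, 10.8 kb), which encode chemotaxis, motor and master regulator proteins, held 1 count in each library. Its neighbours cheY and uspC had 382, 460 and 267 and 228, 535 and 609 counts. The 10 genes belong to the flagella and chemotaxis list and were too low to be measured in it. The other 35 flagellar and chemotaxis genes had a median of 79 counts over the 3 libraries. The next longest run of coding sequences with at most 3 counts in every library had 4.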
